A study of Mus musculus with 6 samples.

How the data were processed

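Total RNA was extracted from 1 homogenised uterine horn per mouse with Trizol and a column kit, labelled with biotin by a whole-transcript method and hybridised to Affymetrix Gene 2.0 ST arrays, per the labels' protocols. The groups were floxed control (animals 2, 3 and 4) and epithelial Porcn knockout (animals 1, 2 and 4). The groups and animal numbers come from the sample titles. The control titles number females, the knockout titles give the knockout and a number only, and the values were treated as 1 animal per array. The sources used here do not say how animals were staged or whether arrays were run in batches.

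The values analysed are the deposited log2 expression values, made by the authors with RMA at gene level in Affymetrix Expression Console, per the labels. RMA corrects background, quantile-normalises the arrays and summarises probes on the log2 scale. The submitters' processing notes also name Transcriptome Analysis Console. Versions, annotation release and filters are not given in the sources used here. Quantile normalisation removes any global shift in RNA content between groups, so a difference here is relative to the other transcripts on the array. The table holds 1 column per sample, all 6 were mapped to a sample by name, and 0 columns were left unmapped. No 2 arrays held identical values. Arrays carry no read depth, no detection calls were used, and the number of arrays limits the precision. Values near the low end of the scale lie close to background, where fold changes are compressed.

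Probe sets were named from the platform annotation supplied with the series. Of 41345 probe sets, 25341 had at least 1 symbol, 1820 of these had several and 16004 had none. The 23521 with a single symbol were tested, and for the 1082 genes with several such probe sets the one with the highest mean over all 6 arrays was kept, which left 22180 genes. In 1 gene the probe sets differed in opposite directions at an unadjusted p under 0.05. Entrez identifiers of 23328 of these probe sets matched a mouse RefSeq gene table (GRCm38), 193 did not and kept their symbol, and 0 symbols changed. No coordinates are given, since the values' genome build is not given in the sources used here. The other 17824 probe sets were fitted as an alternative and named nowhere: 0 passed an adjusted p of 0.05, and 1273 had an unadjusted p under 0.05.

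Differences were tested with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all 22180 genes and a threshold of 0.05. The model had 1 term, the genotype, with 4 residual and 7.56 total degrees of freedom. Intervals are 95% intervals from the same fit. The Porcn difference was also tested by an exact permutation test over the 20 assignments of 6 arrays. Gene lists (31) were written from general knowledge of uterine biology and Wnt signalling before the data were examined. The 30 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry (statmod 1.5.0) beside it. The erythrocyte list had 3 measured members and was not tested. Members were also adjusted over the list alone. A list's score in an array is the mean of its members' values relative to the control mean.

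Genes named in the text were fixed by a rule before the data were examined. They are Porcn, then the 12 largest log2 differences in each direction among genes past the adjusted threshold with non-overlapping groups. Since 0 genes passed, these were filled with genes at an unadjusted p under 0.01 with non-overlapping groups and are given as values that did not pass. Predicted genes, RIKEN clones, small RNAs, pseudogenes, receptor segments and olfactory, vomeronasal and taste receptors were counted but not named. Up to 4 members of each list past the threshold, with the smallest p in the list's direction, and up to 2 of each other list were added. Wnt4, Wnt5a, Wnt7a, Wnt11, Axin2, Lef1, Foxa2, Lif, Esr1 and Pgr were named whatever their values. Genes named outside this rule are said to be so where they appear.

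The limma step was tested on simulated data with the real genes' means and spreads for knockout against control over 22180 genes. It recovered 14 of 50 genes changed 1.5-fold, 39 of 50 changed 2-fold, 48 of 50 changed 4-fold and 50 of 50 changed 8-fold, with 6 false calls among 157. Simulated genes varied independently and with equal spread in both groups. With 157 calls the adjusted threshold is easier to reach than in the real data, where 0 genes passed, so these recovery rates do not carry over. Camera gave a list shifted by 0.5 an adjusted p of 1.5e-09 and called 0 of 29 other lists. Independent genes make false list calls rare by construction. In the real data the estimated correlation within lists ran from -0.08 for oviduct and ciliated cell genes to 0.93 for smooth muscle genes. The camera result on simulated data therefore does not carry over either.

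Alternatives fixed before the data were examined were a filter on probe sets below the median level, every probe set as its own feature, the mean of a gene's probe sets, renewed quantile normalisation, centring on array medians, trended robust moderation, array weights, the animal number as a fixed or random block, other thresholds, other list tests, and leaving out each array in turn. Neutrophil and mucosal lists without members shared with other lists were added after the data were seen, as was camera with an estimated correlation for 7 lists that gained a call in a fit that left out 1 array.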

Results

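Gene expression was measured in whole mouse uterus after loss of Porcupine (Porcn) from the uterine epithelium. Porcn is the acyltransferase that attaches a lipid to Wnt proteins, a step that Wnt proteins need to be secreted and to bind their receptors. Total RNA from 1 whole uterine horn per animal was hybridised to an Affymetrix Gene 2.0 ST array, 1 array per animal. The 6 arrays fell into 2 groups of 3: floxed controls, which carry the conditional allele, numbered 2, 3 and 4, and epithelial Porcn knockouts, numbered 1, 2 and 4. The horn holds epithelium, stroma, smooth muscle, vessels and immune cells, so each value is an average over these tissues. The sources used here give neither the age of the animals nor their hormonal stage. The deposited values were gene-level log2 values, and their medians over 41345 probe sets ranged from 5.42 in knockout 1 to 5.54 in knockout 4. Differences are given as log2 values, knockout minus control, with the standard error (SE) of limma's fit and n = 3 per group. Fold changes are these differences turned to the linear scale. The small number of arrays limits the precision: the median SE over the 22180 genes tested was 0.12, which gave a median margin of 0.29 on either side of the estimate in its 95% interval.

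The first comparison asked whether the targeted gene itself was lower in the knockout horns. Porcn (Entrez gene 53627) read 8.67, 8.53 and 8.45 in controls 2, 3 and 4 and 8.43, 8.75 and 8.62 in knockouts 1, 2 and 4. Its group means were 8.55 ± 0.11 (SD, n = 3) and 8.60 ± 0.16 (SD, n = 3). The difference of 0.05 ± 0.12 (SE) lay within the spread between animals, with a 95% interval of -0.22 to 0.33. The two-sided exact permutation test gave p = 0.80, where 3 animals against 3 cannot go below 0.10, and limma gave an adjusted p of 0.97. Whole-horn RNA also holds Porcn transcripts of cells that are not epithelium, and whether the single probe set for this gene reads the deleted part of the transcript is not given in the sources used here. The Porcn value therefore checks the genotype labels neither way.

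The main comparison asked which transcripts of the whole uterus differed once the epithelium lacked Porcn. The lowest adjusted p belonged to Gja1, which encodes a connexin, the subunit of gap junctions. Gja1 stood at 9.41 ± 0.05 (SD, n = 3) in controls and 8.20 ± 0.10 (SD, n = 3) in knockouts, a log2 difference of -1.21 ± 0.10 (SE) or 2.32-fold lower, with all 3 knockout arrays below all 3 controls. Its adjusted p of 0.0504 just missed the threshold of 0.05. Among the genes named by the rule, next came Syt15, a synaptotagmin, at -1.17 ± 0.12 (SE, adjusted p = 0.15), the secreted protein gene Bpifb5 at 1.68 ± 0.21 (SE, adjusted p = 0.33) and Apcdd1, which encodes a membrane-bound Wnt inhibitor and is itself a Wnt/β-catenin target, at -1.35 ± 0.17 (SE, adjusted p = 0.33). With limma, 0 of the 22180 genes passed an adjusted p of 0.05. At an unadjusted p under 0.05 there were 1331 genes, 725 higher and 606 lower in the knockout, where 1109 would be expected with no difference at all. Non-overlapping groups were seen for 2579 genes, or 11.6%, against the 10% that chance gives for 3 against 3. At least a 2-fold difference was seen for 35 genes higher and 42 lower, and 56 of these also had an unadjusted p under 0.05. Leaving out knockout 1 raised the count at the adjusted threshold from 0 to 17.

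The 12 genes with the largest higher values among non-overlapping genes at an unadjusted p under 0.01 did not pass the adjusted threshold and are given as values. Actc1, the cardiac muscle actin, was highest at 1.79 ± 0.31 (SE), or 3.45-fold. Bpifb5 was 3.21-fold higher, the complement regulator gene Cfi 2.73-fold, the uterine gland chemokine gene Cxcl15 2.33-fold and Sectm1b 1.99-fold. The adhesion receptor gene Adgrg7 was 3.06-fold higher, the glutathione transferase gene Gstm7 2.43-fold and Ajap1, which encodes an adherens junction protein, 2.40-fold. The remaining genes were AA536875 at 2.22-fold, the matrix gene Cilp at 2.06-fold, the cornified envelope gene Sprr2f at 2.04-fold and the hedgehog antagonist Hhip at 1.97-fold. Their SEs ran from 0.21 for Bpifb5 to 0.38 for Adgrg7.

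The 12 largest lower values, none past the adjusted threshold either, began with Il13ra2, a decoy receptor for interleukin 13, at -1.84 ± 0.48 (SE), or 3.57-fold lower. Knockout 1 held most of its spread: Il13ra2 read 6.40 there against 4.61 and 4.38 in knockouts 2 and 4, and 6.82 to 7.13 in controls. The carboxypeptidase-like gene Cpxm2 was 3.34-fold lower and Gzmb, a granzyme of cytotoxic and uterine NK cells, 3.29-fold lower. Lef1, a nuclear partner of β-catenin, was 2.64-fold lower at -1.40 ± 0.37 (SE), with 7.78, 7.59 and 6.21 in knockouts 1, 2 and 4 against 8.54 to 8.65 in controls. The apelin receptor ligand gene Apela was 2.62-fold lower, Apcdd1 2.54-fold, Cpne4 2.45-fold, Clca2 2.34-fold and Gja1 2.32-fold. The calcium-binding protein gene Calb2 was 2.31-fold lower, the glutamate receptor gene Gria4 2.26-fold and Syt15 2.25-fold.

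**Figure D1:**
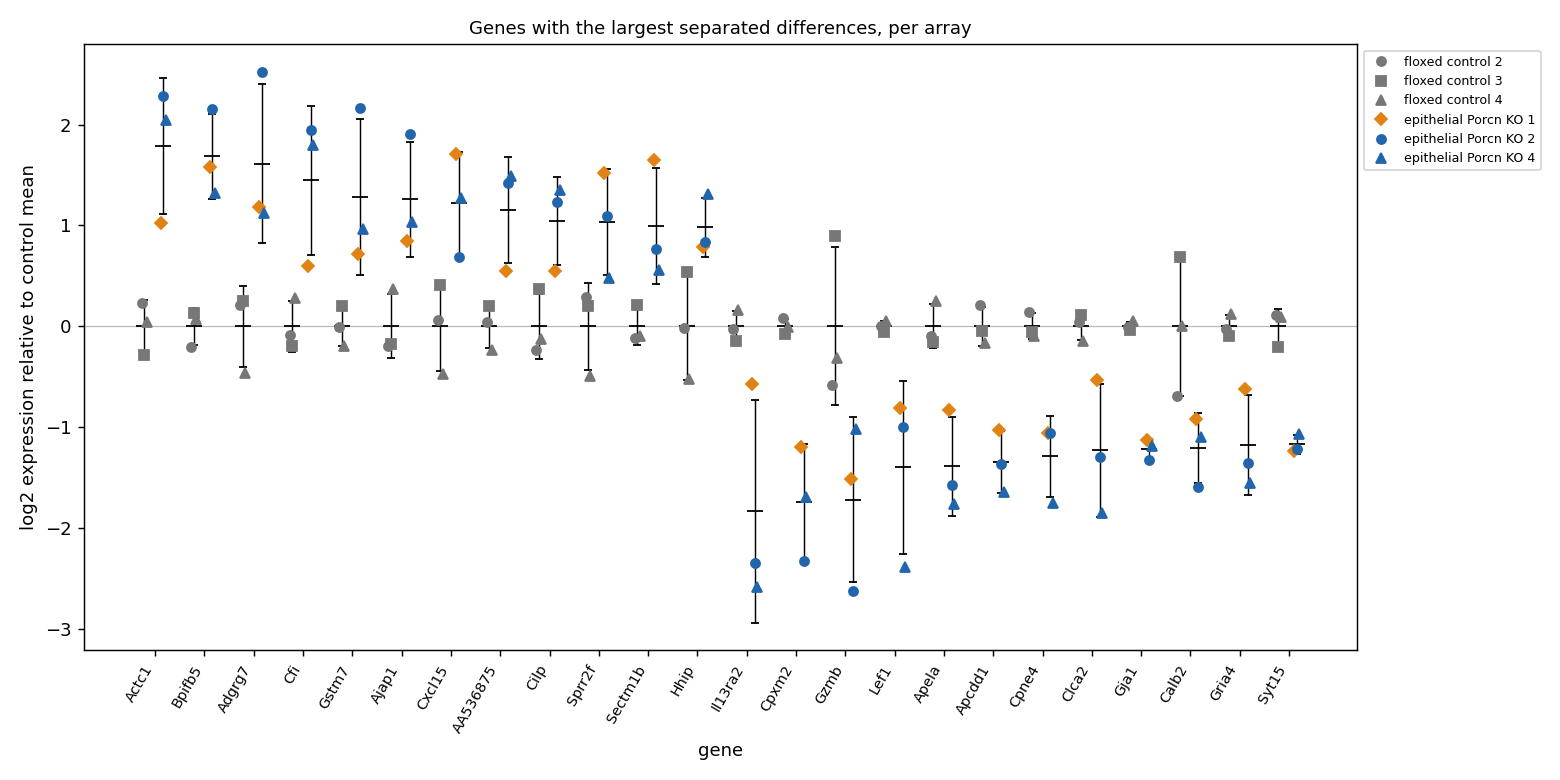
Genes with the largest non-overlapping differences, as log2 expression relative to the control mean (vertical axis) for each gene (horizontal axis); points are single arrays, horizontal marks group means and bars 1 SD. In Gja1 and Syt15 the knockout arrays sit close together, while in Il13ra2 knockout 1, 6.40 on the deposited scale, lies nearer to the controls than knockouts 2 and 4, at 4.61 and 4.38.

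The Wnt pathway was examined through 5 lists. Among the 21 measured targets of Wnt/β-catenin signalling, 13 were lower and 8 higher, and 0 passed when adjusted over all genes. Adjusted over the list alone, 3 fell, 0 rose and 18 did not pass: Apcdd1 (adjusted p = 0.0015), the growth regulator Myc at -0.55 ± 0.13 (SE, adjusted p = 0.037) and Lef1 (adjusted p = 0.042). The Dishevelled antagonist gene Nkd2 stood at -0.72 ± 0.26 (SE) and Axin2, the widely used readout of the pathway, at -0.24 ± 0.09 (SE), from 7.56 ± 0.06 to 7.32 ± 0.05 (SD, n = 3). All 3 knockout arrays were below all controls for both, but neither passed over the list. As a set, the target list was lower than the other genes with limma's camera (adjusted p = 0.042, median -0.04), and not with an estimated correlation (adjusted p = 0.57). That call was lost without control 3 (adjusted p = 0.20), without control 4 (0.089) or without knockout 1 (0.52). Its median ran from -0.15 without knockout 2 to 0.0042 without control 4 and 0.0109 without knockout 1, so its sign depended on single arrays. Without control 2 the median was -0.07 and without knockout 4 -0.11, and the list stayed called.

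Of the 17 secreted Wnt inhibitors, 12 were lower, and 0 passed over all genes or adjusted over the list alone. Sfrp4 stood at -0.39 ± 0.11 (SE), Dkk2 at -0.41 ± 0.12, Draxin at -0.43 ± 0.18 and Sfrp2 at -0.56 ± 0.25. Sfrp2 read 8.96, 8.71 and 7.90 in knockouts 1, 2 and 4 against 9.01 to 9.16 in controls. The list's median was -0.08 with a camera adjusted p of 0.018, against an adjusted p of 0.31 with an estimated correlation, and it did not pass without control 3 (adjusted p = 0.083) or without knockout 1 (0.31). It stayed called with a median further from 0 without control 2 (-0.12), knockout 2 (-0.13) or knockout 4 (-0.12), and with the filter on low probe sets (-0.32, adjusted p = 0.0145). The 19 Wnt ligands did not pass as a set (median -0.07, camera adjusted p = 0.31). With the filter on low probe sets they did (median -0.17, adjusted p = 0.025), while an estimated correlation without that filter gave 0.57. The 19 Wnt receptors (median 0.01, adjusted p = 0.97) and the 15 planar cell polarity genes (median 0.00, adjusted p = 0.78) did not pass as sets either. Adjusted over the ligand list alone, 1 member fell: Wnt16 at -0.99 ± 0.19 (SE, adjusted p = 0.019), 1.99-fold lower, while the other 18 did not pass. The epithelial ligand gene Wnt7a read 5.36 ± 0.07 in controls and 5.60 ± 0.15 in knockouts (SD, n = 3), a difference of 0.24 ± 0.11 (SE, adjusted p = 0.83). The differences for Wnt4 (-0.10 ± 0.12), Wnt5a (-0.27 ± 0.17) and Wnt11 (-0.23 ± 0.18) lay within 2 SE of 0. The receptor genes Fzd3 and Ryk stood at 0.22 ± 0.13 and 0.14 ± 0.09 (SE).

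**Figure D2:**
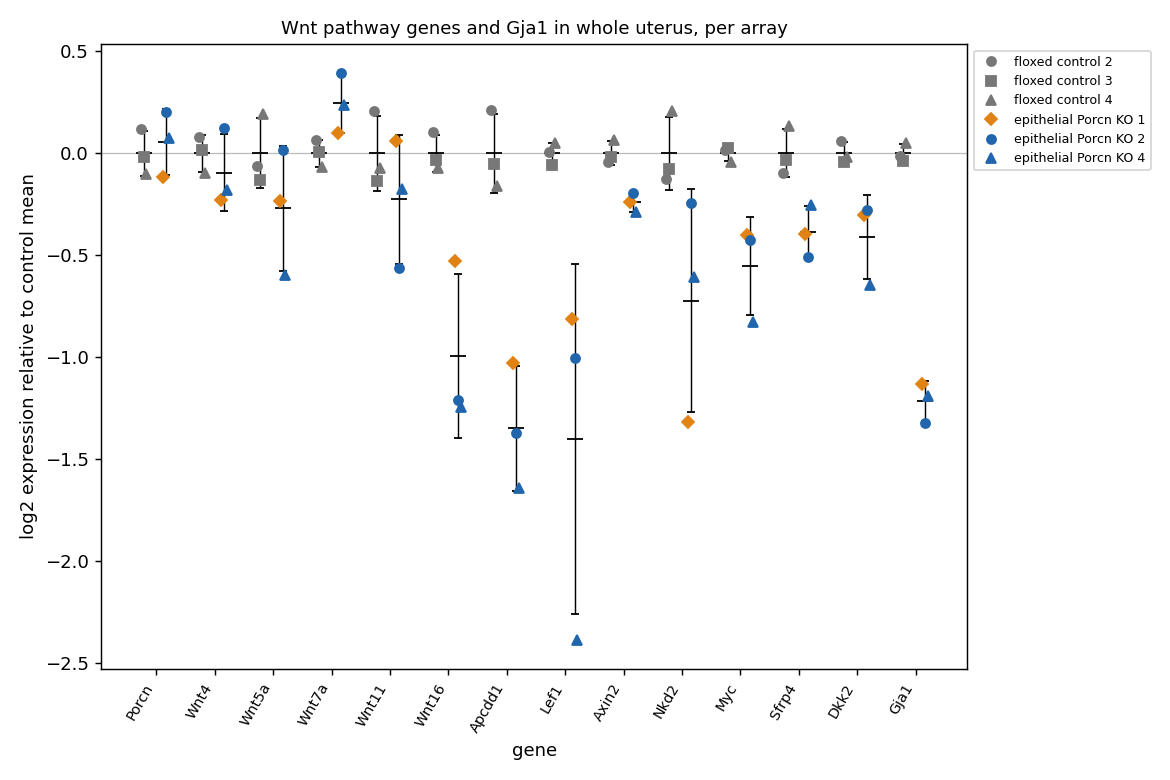
Wnt pathway genes and Gja1, as log2 expression relative to the control mean (vertical axis) for each gene (horizontal axis); points are single arrays, horizontal marks group means and bars 1 SD. Porcn and the ligands Wnt4 and Wnt5a overlap between the groups, while Apcdd1 (-1.35), Lef1 (-1.40), Axin2 (-0.24) and Gja1 (-1.21) are lower in all 3 knockout arrays.

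The pan-epithelial, mucosal defence and estrogen-responsive lists were higher in the knockout horns with camera at the preset correlation, while the gland and stratified squamous lists did not pass. Of the 19 measured pan-epithelial markers all 19 were above the control mean, with a median of 0.39. The list averaged 0.46, 0.43 and 0.15 in knockouts 1, 2 and 4, and 0.16 in control 3, so the groups overlapped. Adjusted over all genes or over the list alone 0 passed. Cldn7 stood at 0.44 ± 0.12 (SE), St14 at 0.41 ± 0.12, E-cadherin (Cdh1) at 0.47 ± 0.14 and Epcam at 0.51 ± 0.16. All 18 mucosal defence genes were higher too (median 0.33, 0 past over the list alone), among them the immunoglobulin transporter Pigr at 0.82 ± 0.24 (SE), complement factor B (Cfb) at 0.97 ± 0.29, the cell-surface mucin Muc1 at 0.56 ± 0.18 and the acute-phase gene Saa3 at 1.63 ± 0.54. Saa3 read 6.55, 6.24 and 8.57 in knockouts 1, 2 and 4 against 5.38 to 5.69 in controls. Estrogen-responsive genes were higher in 12 of 18 (median 0.35, 0 past over the list alone), with Sprr2f at 1.03 ± 0.30, Greb1 at 0.40 ± 0.11 and the iron exporter gene Slc40a1 at 0.86 ± 0.29 (SE). With camera these lists gave adjusted p-values of 8.9e-10, 1.4e-07 and 0.0038, and with an estimated correlation adjusted p-values of 0.31, 0.15 and 0.31. All 3 lists stayed past the preset threshold in 6 of 6 fits that left out 1 array, though the estrogen median ran from 0.18 without control 2 to 0.51 without control 3.

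Endothelial markers were lower in 16 of 16, with a median of -0.43. Adjusted over the list alone 3 fell, 0 rose and 13 did not pass. Those 3 were VE-cadherin (Cdh5) at -0.64 ± 0.15, the angiopoietin receptor Tek at -0.47 ± 0.12 and the transcription factor Sox18 at -0.66 ± 0.18 (SE), each with an adjusted p of 0.032 over the list. Kdr, a receptor for vascular endothelial growth factor, stood at -0.43 ± 0.13. The endothelium list gave a camera adjusted p of 6.3e-10 and an adjusted p of 0.31 with an estimated correlation, and was called in 6 of 6 fits that left out 1 array, with a median of -0.28 without knockout 2. Stromal markers were lower in 15 of 18 (median -0.14, 0 past over the list alone), with Vcan at -0.45 ± 0.12, Hand2 at -0.46 ± 0.21, Thy1 at -0.57 ± 0.29 and Dcn at -0.20 ± 0.12 (SE). Their camera adjusted p was 0.0097, with an adjusted p of 0.57 with an estimated correlation, and the call was lost without control 4 (median -0.08, adjusted p = 0.066) and without knockout 1 (0.46, median 0.0064). The median was -0.08 without control 2 and -0.23 without knockout 4. Thy1 was lowest in knockout 2 (7.93, against 9.22 and 8.68 in knockouts 1 and 4) and Hand2 in knockout 4 (7.21, against 8.07 and 7.79 in knockouts 1 and 2). Smooth muscle markers, measured in the same RNA, averaged -0.59 in knockout 1 but 0.35 and 0.56 in knockouts 2 and 4 relative to the control mean (list adjusted p = 0.47).

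Among the steroid hormone receptor genes, Esr1 differed by -0.02 ± 0.10 and Pgr by -0.13 ± 0.15 (SE), and the sign of Esr1 turned when each array was centred on its median (0.0042). Progesterone-responsive genes were lower in 13 of 16 (median -0.19, camera adjusted p = 0.032, adjusted p = 0.31 with an estimated correlation). Adjusted over the list alone 1 fell and 1 rose: Il13ra2 (adjusted p = 0.043) and Indian hedgehog (Ihh), at 0.57 ± 0.12 (SE, adjusted p = 0.027), while 14 did not pass. Endothelin 1 (Edn1) stood at -0.26 ± 0.12 and Fkbp5 at -0.25 ± 0.13 (SE). This call was lost without control 3 (adjusted p = 0.094), control 4 (0.089), knockout 2 (0.21, median -0.12) or knockout 4 (0.098). In the hedgehog list 2 of 13 members rose when adjusted over the list alone, Ihh (adjusted p = 0.022) and Hhip at 0.98 ± 0.27 (SE, adjusted p = 0.047), and the list as a set did not pass (median 0.06, adjusted p = 0.47).

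Gland genes did not pass as a set (12 genes, median 0.05, mean -0.18, adjusted p = 0.56), but were called higher without knockout 2 (median 0.21, adjusted p = 0.041, and 0.79 with an estimated correlation). Within the list 1 gene, Cxcl15, rose at 1.22 ± 0.30 (SE, adjusted p = 0.046 over the list alone). Among the members that did not pass, 3 named after their values were seen had wide spreads and lay within 2 SE of 0: Spink1 at -1.94 ± 1.18, Prss29 at -1.89 ± 0.96 and Prss28 at -1.03 ± 0.66 (SE). Foxa2, the transcription factor of uterine glands, differed by 0.11 ± 0.19 (SE), and the implantation cytokine gene Lif by -0.05 ± 0.41, with 7.31, 5.39 and 6.32 in knockouts 1, 2 and 4 against 6.32 to 6.52 in controls. Aldh1a1 stood at 1.05 ± 0.44 (SE), with 7.81, 9.58 and 7.84 in knockouts 1, 2 and 4 against 7.22 to 7.45 in controls. The stratified squamous list (23 genes, median 0.06, adjusted p = 0.49), the Müllerian duct patterning list (15 genes, median -0.10, adjusted p = 0.47) and the proliferation list (29 genes, median -0.05, adjusted p = 0.20) did not pass either, though the Müllerian list was called lower without knockout 2 (median -0.14, adjusted p = 0.041, and 0.48 with an estimated correlation). Without knockout 1 the proliferation list was called lower (median -0.19, adjusted p = 5.7e-05) and the smooth muscle list higher (median 0.40, adjusted p = 6.1e-11). The proliferation list was also called lower without control 4 (adjusted p = 0.0020). With an estimated correlation neither passed without knockout 1 (adjusted p = 0.49 and 0.45), nor did proliferation without control 4 (0.78). Estimated correlations in fits without 1 array were added after the data were seen.

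Inflammatory lists were higher mainly in knockouts 2 and 4. Neutrophil markers were above the control mean in 13 of 16 (median 0.48, camera adjusted p = 7.1e-04, adjusted p = 0.57 with an estimated correlation), and the list averaged 0.05, 1.03 and 0.71 in knockouts 1, 2 and 4. Lactoferrin (Ltf) stood at 1.92 ± 0.82, lipocalin 2 (Lcn2) at 1.42 ± 0.67, Clec4d at 1.12 ± 0.39 and S100a9 at 0.81 ± 0.28 (SE). Ltf and Lcn2 are also made by uterine epithelium and stand in the mucosal and estrogen lists, and without both the neutrophil list still passed camera (adjusted p = 0.0054), an alternative added after the data were seen. The list did not pass without knockout 2 (median 0.18, adjusted p = 0.089), and its median was 0.94 without knockout 1. Macrophage markers were higher in 15 of 18 (median 0.30, camera adjusted p = 0.013, adjusted p = 0.79 with an estimated correlation), with Lyz2 at 0.71 ± 0.20, Cd14 at 0.86 ± 0.27, Ms4a7 at 0.60 ± 0.25 and Cd68 at 0.67 ± 0.28 (SE). This call was lost without control 4 (median 0.18, adjusted p = 0.27) or knockout 4 (median 0.06, adjusted p = 0.47).

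Interferon response genes were higher in 16 of 17 (median 0.39, camera adjusted p = 0.0085, adjusted p = 0.79 with an estimated correlation). The list averaged -0.31, 0.31 and 1.04 in knockouts 1, 2 and 4, and without knockout 4 its median was -0.02 (adjusted p = 0.71), so that animal carried the call. Without knockout 1 the median was 0.83. Oasl1 stood at 0.66 ± 0.26, Cxcl10 at 0.91 ± 0.40, Ifit2 at 0.28 ± 0.19 and Mx1 at 0.43 ± 0.31 (SE). Immediate early genes, which respond within minutes to stimulation and to tissue handling, were lower in 14 of 16 (median -0.27, camera adjusted p = 9.6e-05, adjusted p = 0.57 with an estimated correlation). Control 3 stood apart at 0.62 above the control mean, and without it the list did not pass (median -0.03, adjusted p = 0.12), while the median was -0.42 without control 2 and -0.50 without knockout 1. Egr1 stood at -1.12 ± 0.31, Klf4 at -0.41 ± 0.15, Egr3 at -0.71 ± 0.31 and Fos at -0.75 ± 0.36 (SE). In each of the neutrophil, macrophage, interferon and immediate early lists 0 members passed over all genes or over the list alone.

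**Figure D3:**
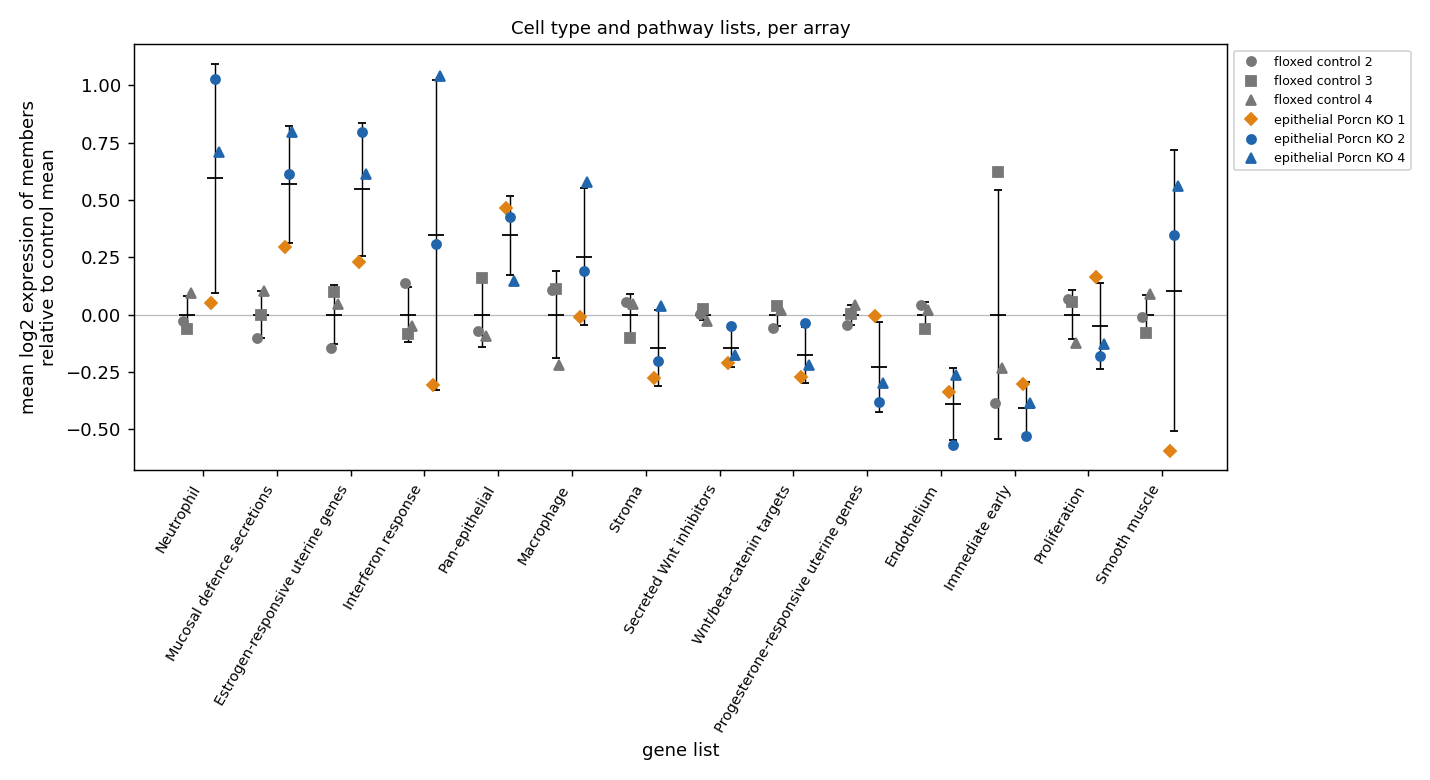
Mean log2 expression of each list's members relative to the control mean (vertical axis) for the 12 lists past the camera threshold and the proliferation and smooth muscle lists (horizontal axis); points are single arrays, horizontal marks group means and bars 1 SD. Endothelial markers are lower in all 3 knockout arrays (-0.34, -0.57 and -0.26), while smooth muscle places knockout 1 (-0.59) below and knockouts 2 and 4 above the controls.

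In all, 12 of 30 tested lists passed camera with a preset correlation, 6 higher and 6 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.15), and with fry, which tests whether a list's genes move one way on balance, 0 passed (lowest adjusted p = 0.059, for mucosal defence). Fry's test for change in either direction called 1 list, the Wnt/β-catenin targets (adjusted p = 0.017). Knockouts 1, 2 and 4 each correlated more closely with the controls (mean Pearson r across genes 0.989, 0.987 and 0.989) than with the other knockouts (0.983, 0.986 and 0.986). Knockout 1 lowered the latter means of knockouts 2 and 4, which correlated with it at 0.9831 and 0.9832 but with each other at 0.9892. With single controls, knockout 2 correlated at 0.9864 to 0.9879 and knockout 4 at 0.9881 to 0.9893. The root mean square SD within groups was 0.25 in knockouts against 0.18 in controls. The controls correlated with each other at 0.993 to 0.994.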

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

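The alternatives were fixed before the data were examined, except that the neutrophil and mucosal lists without shared members were added afterwards, and both still passed (adjusted p = 0.0054 and 9.3e-06), as was the estimated correlation for the 7 lists that gained a call with 1 array left out, where 0 passed (adjusted p from 0.43 for antigen presentation to 0.79 for gland and mesothelium genes). The count of 0 genes became 1 with the filter on low probe sets, the mean of probe sets, trended robust moderation, array weights, the random replicate block or an adjusted p under 0.10, and 56 at an unadjusted p under 0.05 with a 2-fold difference. The gene passing was Gja1 under each of the first 5. The count stayed 0 with renewed quantile normalisation, median centring, the fixed replicate block, every probe set or a 1.5-fold minimum. Leaving out 1 array gave 0 to 17, the 17 without knockout 1. Over the 22180 genes the count at an unadjusted p under 0.05 (1331) ran from 852 without control 2 to 2460 without knockout 1. It was 805 with the filter on low probe sets, which tested fewer genes, and 2345 over all 41345 probe sets. Lists past the threshold numbered 11 to 13 under the other settings run and 8 to 13 with 1 array left out, but 0 with an estimated correlation and 0 with fry. They were not run with the random replicate block or with every probe set as a feature. Knockout 1 and control 3 share their number with no other array, so the fixed replicate block compares knockouts 2 and 4 with controls 2 and 4 only. With it the Wnt/β-catenin target (adjusted p = 0.82), Wnt inhibitor (0.30) and stroma (0.18) lists did not pass, while the smooth muscle (5.3e-10) and proliferation (0.0068) lists did. With array weights the target (0.29) and inhibitor (0.079) lists did not pass either, and proliferation (0.0038) and smooth muscle (0.0016) did. With the mean of probe sets the target list did not pass (0.13). With the filter on low probe sets the progesterone list did not pass (0.0691), while the Wnt ligand (0.025) and T and NK cell (0.0135) lists were called lower, and medians were further from 0 for the inhibitor (-0.32), estrogen (0.56) and mucosal (0.65) lists. No estimated correlation was run with the fixed block, array weights or this filter. In the main fit it gave camera adjusted p-values of 0.93 for smooth muscle, 0.85 for proliferation, 0.57 for Wnt ligand and 0.80 for T and NK cell genes.

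Whether equal animal numbers pair the animals is not given in the sources used here. The groups shared 2 numbers, and the deviations of these same-number arrays from their group means correlated at 0.05 and 0.09. Arrays with different numbers gave -0.15 to 0.18. With 2 such pairs these values cannot tell whether the animals were paired. The consensus correlation of the random replicate block was 0.11. Array weights were lowest for knockout 1 (0.38).

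For the 24 largest genes 340 results under alternatives kept direction and side of the threshold, 14 passed it, and 0 changed sign. These genes were picked for non-overlapping groups, so leaving out or weighting arrays could not turn their sign, and the 0 is no evidence of stability. Among other genes and lists, several results changed sign. Porcn ran from -0.0201 to 0.14 with 1 array left out (negative without knockout 2), Foxa2 from -0.0551 to 0.27, Lif, whose values spread widely, from -0.53 to 0.42, Pgr from -0.27 to 0.0034, Esr1 from -0.0527 to 0.0440 and H2-DMb1, a gene of the antigen presentation list, from -0.0087 to 0.20. Esr1 was also positive with median centring (0.0042), array weights (0.0153) and the fixed replicate block (0.0465), where H2-DMb1 was -0.0111. The Wnt/β-catenin target list, called lower, had a positive median with array weights (0.0203), the fixed replicate block (0.0732), without control 4 (0.0042) and without knockout 1 (0.0109), as did the stroma list without knockout 1 (0.0064). With 1 array left out, the interferon list, called at a median of 0.39, ran from -0.0162 to 0.83, and the antigen presentation list from -0.16 (called lower, adjusted p = 0.0049) to 0.15, both lowest without knockout 4. The cause was not tested. No detection calls were used, so signal over background limits dim genes to an unknown extent.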

Other observations

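Tests chosen after the result, or list medians bearing on it, had been seen were those of knockout 1 on the genes called without it and against held-out controls, of the stroma list without 1 array, of a larger epithelial share, of hormonal stage, of fewer stromal or endothelial cells and of the other target list members, while the position of knockout 1, the epithelial and endothelial lists without 1 array and the splits were set before. Other cell types of the horn were read through lists that did not pass. T and NK cell genes were lower in 10 of 16 (median -0.13, adjusted p = 0.31), were called lower without knockout 4 (-0.25, adjusted p = 0.012, and 0.44 with an estimated correlation) and had a median of 0.06 without control 4, with Gzmb at -1.72 ± 0.48 and Cd8a at 0.41 ± 0.12 (SE) going opposite ways. B and plasma cell genes (median 0.09, adjusted p = 0.43, Cd79b at 0.33 ± 0.11), eosinophil and mast cell genes (median 0.05, mean -0.06, adjusted p = 0.78, Cpa3 at -0.97 ± 0.49) and antigen presentation genes (median 0.06, adjusted p = 0.96, but -0.16 and 0.0049 without knockout 4, and 0.43 there with an estimated correlation) did not pass as sets. Neither did matrix turnover genes (median 0.02, adjusted p = 0.99). Tissues that a dissected horn can carry along gave no call with all arrays: ovary (median -0.02, adjusted p = 0.47), oviduct and ciliated cells (median 0.01, adjusted p = 0.56), adipose tissue (median -0.06, adjusted p = 0.47) and mesothelium (median -0.00, adjusted p = 0.99), though mesothelium was called lower without knockout 2 (-0.25, adjusted p = 0.041, and 0.79 with an estimated correlation). The 3 erythrocyte genes measured, too few to test, had a median of -0.11.

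Without knockout 1, limma called 17 genes, 5 higher and 12 lower, at an adjusted p under 0.05. These names were chosen after their values were seen. The lower genes included Il13ra2 (5.54-fold, adjusted p = 0.014), the estrogen-metabolising cytochrome Cyp1b1 (2.96-fold), Wnt16 (2.34-fold), Apcdd1 (2.84-fold), Apela (3.17-fold) and Gja1 (2.39-fold). The higher ones were the secretory cell gene Clca1 (7.09-fold), Actc1 (4.50-fold), the cardiac troponin gene Tnnt2 (2.44-fold), Cfi (3.66-fold) and AA536875 (2.74-fold). Knockouts 2 and 4 differed from the control mean in a correlated way across genes (r = 0.44), and knockout 1 did so less with either (0.12 and 0.05). The shared control mean alone gave r = 0.14 in 100 simulated draws with no effect. The covariance was 0.037 for knockouts 2 and 4, and 0.0097 and 0.0037 for knockout 1 with each, against 0.010 simulated. Genes are not independent replicates.

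Knockout 1 correlated more closely with the controls (mean r 0.989) than with the other knockouts (0.983), as knockouts 2 (0.987 against 0.986) and 4 (0.989 against 0.986) did by smaller margins. The means of knockouts 2 and 4 with the other knockouts include knockout 1, and these 2 arrays correlated with each other at 0.9892. The controls correlated with each other at 0.993 to 0.994, above the 0.988 to 0.990 of knockout 1 with each control. In the test set beforehand, the median position of knockout 1 over 100 genes chosen without it was 0.0685 on a scale from the control mean (0) to knockouts 2 and 4 (1). That is below the limit set for a control horn under a wrong label. Held out in the same way, though, controls 2, 3 and 4 lay at 0.30, 0.40 and 0.35, above that limit, and knockouts 2 and 4 at 0.64 and 0.39. The position therefore does not tell a control from a knockout here. With 100 genes chosen from 2 controls and knockouts 2 and 4, the remaining control and knockout 1 lay at 0.02 and 0.11, 0.10 and 0.22, and 0.14 and 0.08, so over these genes neither was always the nearer to the controls. Over 17 genes chosen in that way, the remaining control lay at -0.03, 0.09 and 0.08 and knockout 1 at 0.30, 0.44 and 0.32, so the control was the nearer each time. At the 17 genes called without knockout 1, that array lay on the other knockouts' side of the control mean at 13. The positions over 100 and over 17 genes differ, those of knockout 1 rest on 1 array, and 3 controls are a small reference. A wrong label therefore stays open, as do fewer deleted cells, another hormonal stage and a smaller share of muscle (smooth muscle list at -0.59), which were not tested.

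The pan-epithelial and mucosal lists were higher and the endothelial and stromal lists lower in the knockout, calls that were lost with an estimated correlation (adjusted p = 0.31 for pan-epithelial, 0.15 for mucosal, 0.31 for endothelial and 0.57 for stromal genes). The gland list was not called higher (adjusted p = 0.56). A larger epithelial share alone would lower the other tissues alike. Of the stroma, smooth muscle, endothelium and macrophage lists, the highest, macrophage (0.25 ± 0.20), exceeded the lowest, endothelium (-0.39 ± 0.10), by 0.64 ± 0.20 (SE over arrays). The pair was picked as the extremes after the values were seen, so this gap decides nothing. A larger epithelial share stays open, as does macrophage entry on top of such a shift. A single knockout array did not carry the pan-epithelial or endothelial part, of which at least 0.77 was left without any 1 of them, whereas the stromal part (-0.15 ± 0.11) kept 0.56 of its mean without knockout 1 but lost its median (0.0064) and its call (adjusted p = 0.46), so dependence on that array stays open. A stage with estrogen acting on secretion and division together would raise both lists, and the estrogen list exceeded the proliferation list by 0.60 ± 0.30, a margin barely over 2 SE. A stage at which secretion is high and division low was not tested, and a response of the epithelium to Porcn loss may be the source but stays a hypothesis with stage unrecorded.

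Apcdd1, Lef1, Axin2 and Gja1 were lower in all 3 knockout arrays. Their mean difference of -1.05 ± 0.17 lay below the -0.39 ± 0.10 of the endothelium list, a gap of -0.66 ± 0.23 (SE), but the genes were picked after their falls were seen, so this decides nothing, and Axin2 and Lef1, named beforehand, lay -0.43 ± 0.33 from that list, within 2 SE. Fewer endothelial or stromal cells therefore stay open as the cause. The other 18 members of the target list averaged -0.0403 ± 0.0954, with 10 lower. That mean lies within 2 SE of 0, the outcome predicted if these genes were picked out by their values. Members that go both ways, Myc among those that fell, leave this open. Lower Wnt signalling to cells next to the epithelium may be the source, a hypothesis that whole-horn RNA cannot place in a tissue.

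The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes past the adjusted threshold and the other splits at most 0, so 10 of 10 gave as many. At an unadjusted p under 0.05 the real split gave 1331 genes and 3 of 10 splits gave as many. The highest other split, 1829, set controls 2 and 3 with knockout 1 against control 4 with knockouts 2 and 4, and the next, 1389, set control 2 with knockouts 2 and 4 against the rest. The real split called 12 lists and the highest other split also 12, so 2 of 10 gave as many. The other splits called 9, 1, 9, 12, 10, 9, 11, 4 and 11 lists, so at the preset correlation most other groupings of these arrays gave nearly as many calls.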
